A study of Mus musculus with 6 samples.

How the data were processed

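The series measured polyadenylated RNA of mouse oocytes arrested at metaphase II (MII), the stage at which an oocyte waits for fertilisation. Libraries were made by Smart-seq2, a full-length cDNA method that amplifies the RNA of single cells by PCR; the labels' protocols named no molecular identifiers. The 6 samples fell into 4 groups. One sample of 59 single oocytes came from aged mice and one sample of 35 single oocytes from young mice, with 1 library per oocyte. The other 4 samples were pools of 10 oocytes labelled young, 2 treated with control short interfering RNA (siCtrl) and 2 with short interfering RNA against Plat (siPlat). The labels named no animals, so the spread between the siCtrl or siPlat replicates may be technical, and the p-values below measure only the spread between these samples.

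The authors deposited whole-number counts of reads per gene in 2 tables, one for the pools and one for the single oocytes, neither of them normalised. STAR 2.7.10b, HTSeq 0.13.5 and the genome build mm10 were named per the submitters' processing notes, which did not assign a role to each tool. The annotation, any filter on genes before deposit and the strand setting of the counting were not given in the sources used here, so overlapping and antisense genes cannot be told apart, and genes of the Pramel and Zfp families, whose members are close copies, are uncertain because reads can be split between copies. The table of pools listed 14165 genes, 101 of them at 0 in all 4 libraries, and held 0 mitochondrially encoded genes. The single-oocyte table held 54658 gene entries and 92 ERCC spike-in entries, which are synthetic RNAs added to a lysate in a known amount. ERCC counts stayed out of the gene totals and tests. All 94 oocyte columns and 4 pool columns were used, and the header of the single-oocyte table ended in 1 further column without a name, which held no values.

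Positions, gene types, transcript lengths and GC content came from GENCODE and RefSeq annotations of GRCm38, the assembly that mm10 names, and 14136 of the symbols in the table of pools had a position. Of these symbols, 13926 were matched to the single-oocyte table, 13661 of them under the same symbol and the rest through synonyms that are not the official symbol of another gene.

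For the pools, the main test was the quasi-likelihood test of edgeR 4.0.16 (robust fit) in R 4.3.3, on counts with TMM factors, after the default expression filter of edgeR (a minimum count of 10 and a minimum total of 15), with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error (SE) of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. CPM values of the pools are after TMM scaling. They give relative levels of polyadenylated RNA and no amounts per oocyte. A fold against a group with 0 counts was given as a lower bound, computed with 3 counts over the group. In a simulation of this comparison over 10775 genes, the test recovered 53 of 100 genes changed 2-fold and 95 of 100 genes changed 4-fold, with 19 false calls, and made 2 calls where nothing was changed.

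For the single oocytes each age was 1 sample, so no test was made, and no p-value or count of changed genes was derived from the oocytes. Counts were summed over the oocytes of a group and given as CPM, with exact Poisson intervals at 95% confidence; shares of oocytes have exact binomial intervals. The Poisson intervals treat reads as independent, which PCR reads without molecular identifiers are not, so they may be too narrow even for counting error. The binomial intervals and the limits set by a count of 0 treat oocytes as independent draws, although the labels named no animals. None of them covers the spread between animals or samples. Log2 ratios of aged over young used a pseudocount of 1 CPM. A gene list was described by the median log2 ratio of its members with at least 5 CPM in the mean of both groups, and by the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins. In a simulation over 8303 genes, 1 of 20 unshifted lists and 20 of 20 lists shifted by 0.5 on the log2 scale lay above the range of 95% of random lists. Random lists were matched on expression and not on how members vary together. A percentile may therefore be too extreme for a list whose members do, such as ribosomal proteins.

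Before the data were examined, 32 gene lists with 863 members were fixed from textbook knowledge; 726 members were found in the table of pools and 855 in the single-oocyte table. The lists covered plasminogen activation, Erk1/2 cascade components, transcriptional targets and feedback inhibitors of Erk1/2, immediate early genes, pro-apoptotic genes, anti-apoptotic genes, necroptosis and pyroptosis, ferroptosis and iron handling, autophagy and lysosome, p53 targets and DNA damage, the unfolded protein response, heat shock proteins, antioxidant defence, PI3K with Akt and mTOR, interferon-stimulated genes, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, mitochondrial dynamics, glycolysis and pentose phosphate, cytosolic ribosomal proteins, proteasome subunits, meiotic maturation and MII arrest, meiotic cohesin and spindle checkpoint, egg activation and calcium signalling, maternal mRNA clearance and translational control, DNA methylation and chromatin regulators, small RNA machinery, and oocyte markers with maternal effect genes. Markers of cumulus and granulosa cells, of blood and immune cells, of stroma, theca and endothelium, and genes of zygotic genome activation were included to measure RNA of other cells or stages. In the pools, lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry; smaller lists have member values only.

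The rule for named genes was also fixed before the data were examined. In the pools it took Plat, then the 12 highest and the 12 lowest log2 fold changes among called genes with an average log2 CPM of at least 3 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p. For age it took Plat, then the 12 highest and the 12 lowest log2 ratios among genes with at least 20 CPM in the higher group, a count in at least 50% of its oocytes, and the same direction in the mean and the median over oocytes, and up to 4 members of each list with the largest ratio and at least 10 CPM. Unnamed gene models were passed over, and the values of some list members are not reported here.

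For the pools, the alternatives fixed beforehand were RLE size factors, upper-quartile scaling, no filter, a filter of 50 counts in both libraries of a group, the replicate number as a block, each library left out, DESeq2 1.42.0 and limma-voom. For age they were the mean and the median over oocytes in place of the sum, thinning to 4280000 counts per oocyte, TMM factors, totals without mitochondrially encoded genes, other pseudocounts (0.1 and 5 CPM), other expression minimums (1 and 20 CPM), and leaving out the deepest oocyte of each group. Added after seeing the data were the age comparison without libraries whose mitochondrially encoded share of gene counts was above 5%, scaling to ERCC counts (with and without those libraries), and the count of called genes without a segment of chromosome 4 and without genes with almost no counts in a group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.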

Results

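The data consisted of 4 pooled libraries and 94 single-oocyte libraries. Total gene counts were 17475952 and 13442260 in siCtrl 1 and 2 and 12142884 and 13139499 in siPlat 1 and 2, with 13137, 13178, 12555 and 12662 genes having a count. Within each group the replicates differed by more than counting error, with a chi-square per degree of freedom of 19.3 for siCtrl and 30.8 for siPlat. Single oocytes held 2018226 to 9502184 gene counts in the aged sample (median 5928662) and 5480050 to 11894782 in the young sample (median 8564642).

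The first comparison asked what changes in the transcriptome of MII oocytes when Plat is depleted. Plat encodes tissue-type plasminogen activator, a secreted serine protease that converts plasminogen to plasmin. The gene lies on chromosome 8 at 22757727 to 22782844 (mm10), and reads were counted per gene, with no record of where in it they lay. Plat was at 441 and 439 CPM in siCtrl 1 and 2 and at 51.4 and 39.0 CPM in siPlat 1 and 2. The mean fell from 440.3 ± 1.40 CPM to 45.2 ± 8.72 CPM (SD, n = 2 per group), a log2 fold change of -3.28 (SE 0.19) or 9.74-fold (edgeR adjusted p = 6.21e-06).

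**Figure D1:**
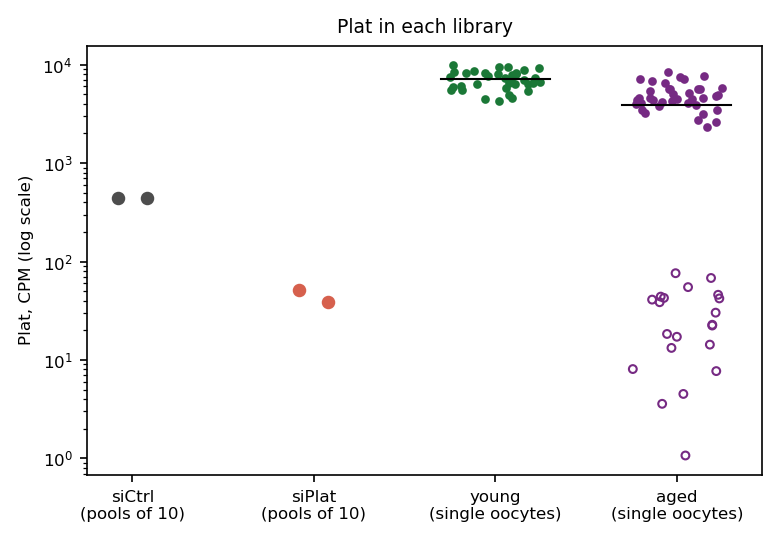
Plat in each library in CPM on a log axis, with 1 point per library for the siCtrl and siPlat pools and for single young and aged oocytes; horizontal lines are medians over oocytes and open circles are aged oocytes with a mitochondrially encoded share above 5%. Both siPlat pools lie below both siCtrl pools, and the 21 open circles lie between 1.07 and 76.1 CPM.

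Besides Plat, genes with known roles in the oocyte fell in siPlat, among them Mos, Astl and Gdf9. Mos, the kinase that activates the Erk pathway in the oocyte and holds it in MII arrest, fell from 797 ± 164 to 255 ± 34.2 CPM (log2 fold change -1.64, SE 0.18, edgeR adjusted p = 0.00101). Astl, the egg protease that cleaves the zona pellucida after fertilisation, fell from 80.7 ± 15.3 to 26.2 ± 4.38 CPM, and Gdf9, a growth factor secreted to the cumulus cells, from 2920.5 ± 136 to 1635 ± 127 CPM. Transcripts that rose included Prdx1, a peroxide-reducing peroxiredoxin, from 4473 ± 299 to 9281 ± 950.4 CPM, and Dazl, an RNA-binding activator of translation, from 1759 ± 158 to 3329 ± 334 CPM. In all, 394 of 11136 tested genes were called by edgeR, 237 higher and 157 lower in siPlat, and 225 of them changed at least 2-fold. With 0 mitochondrially encoded genes in the table of pools, the pools could not be checked for oocytes of high mitochondrial share. Whether the state of the pooled oocytes adds to these changes was not tested.

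Among the 12 genes named for the highest increases, Hsd17b13, which encodes a lipid droplet protein, rose from 2.81 to 53.01 CPM (log2 fold change 4.22, 18.6-fold). The kinase gene Stk32a rose from 17.1 to 82.8 CPM (2.27), and Rp9 (3.07), Basp1 (3.06), Spink2 (2.48), Sft2d3 (2.06) and Tspan12 (1.82) also rose. The remaining 5 lie near each other on chromosome 4. They are Pramel27, with 0 counts in both siCtrl libraries and 65.9 CPM in siPlat (at least 699.9-fold higher), and the zinc finger genes Zfp979 (42.9 to 404 CPM, log2 fold change 3.24), Zfp992 (2.43), Zfp984 (2.16) and Zfp980 (2.02). Their levels are uncertain because family members are close copies, and 12 of the 42 tested genes of that segment were called against 3.54% of all tested genes.

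Among the 12 named for the largest decreases, Nfya, a subunit of the CCAAT-binding factor NF-Y, fell from 231 to 41.9 CPM (log2 fold change -2.46). The vesicle fusion gene Vamp3 fell from 74.6 to 17.9 CPM (-2.06) and the endoplasmic reticulum gene Bcap29 from 48.7 to 8.43 CPM (-2.53). Agbl2, a tubulin carboxypeptidase gene, was at 38.5 CPM in siCtrl and at 0 counts in siPlat (at least 316-fold lower). In young single oocytes, which were separate libraries, Agbl2 was at 0 to 5.71 CPM (median 1.28), nearer to siPlat than to siCtrl. The others were Swap70 (-2.95), Trim21 (-2.64), Btla (-2.44), Cldn34b2 (-2.29), Pak3 (-2.11), Pigt (-2.07), Ergic3 (-2.04) and Pramel48 (-2.79), the last with the same uncertainty about copies.

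**Figure D2:**
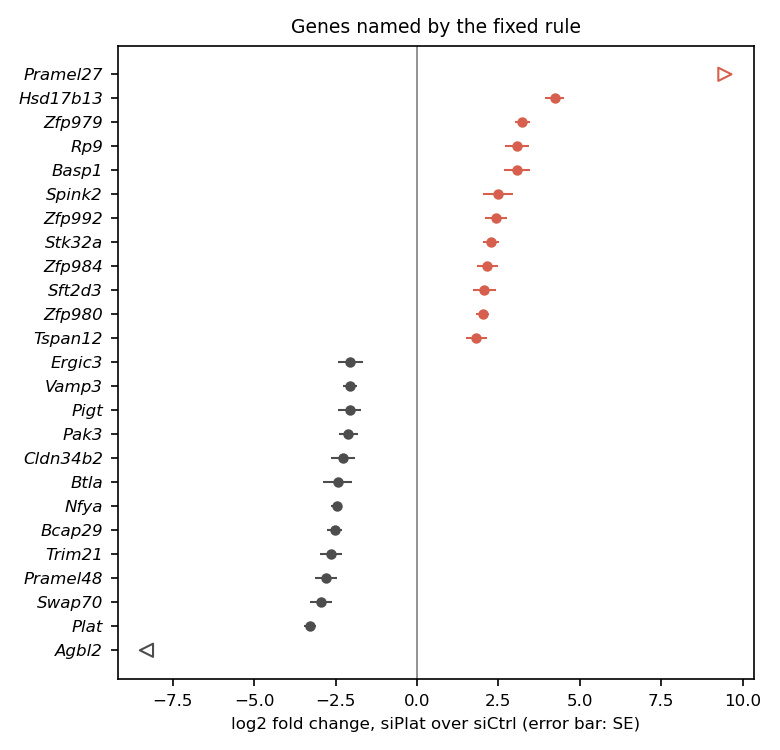
Log2 fold change of siPlat over siCtrl for Plat and the 24 genes named by the fixed rule, with bars of 1 SE from edgeR on 4 pooled libraries. Open triangles mark Pramel27 and Agbl2, which had 0 counts in a group and are drawn at their lower bounds; Plat lies at -3.28.

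Grouped by list, oocyte markers with maternal effect genes held the most calls: 7 of 31 tested members fell, 1 rose and 23 did not pass. Besides Astl and Gdf9, Zp1 of the zona pellucida (-1.31), the linker histone gene H1f8 (-0.65), Zar1l (-1.12) and the subcortical maternal complex genes Tle6 (-0.83) and Khdc3 (-1.17) fell, and Uchl1 rose (0.70). Adjusted over the list alone, 12 fell and 4 rose. Of 20 genes of meiotic maturation and MII arrest, Mos, Bora (-1.14) and Fbxo43 (-0.72), the inhibitor of the anaphase-promoting complex in MII, fell and 17 did not pass; adjusted over the list alone, 4 fell. In meiotic cohesin and spindle checkpoint, Bub1b fell (-0.93) among 30 members, with 2 lower and 3 higher adjusted over the list alone. In egg activation and calcium signalling, Astl fell among 18 members, with 1 lower and 1 higher adjusted over the list alone. Of 27 genes of maternal mRNA clearance and translational control, Dazl rose and Pabpn1l fell (-0.87), against 1 higher and 2 lower adjusted over the list alone. Of 32 chromatin regulators, Kdm1a rose (0.78), with 4 higher and 1 lower adjusted over the list alone.

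In signalling and stress lists few members passed. Of 29 Erk1/2 cascade components, Mos was the only 1 to fall, 1 rose and 27 did not pass, and the counts were the same adjusted over the list alone. Of 17 Erk1/2 targets and feedback inhibitors, the phosphatase gene Dusp1 fell (-0.81), with 1 lower and 1 higher adjusted over the list alone. Dusp1 was also the single call among 9 immediate early genes, where 2 fell adjusted over the list alone. In plasminogen activation, Plat was the single call of edgeR among 10 members; its inhibitor Serpine2 was 0.53 higher on the log2 scale (edgeR adjusted p = 0.0765), and 2 fell and 1 rose adjusted over the list alone. Of 20 PI3K, Akt and mTOR genes, Deptor fell (-0.85) on both adjustments. Of 26 genes of the unfolded protein response, the stress sensor gene Ern1 fell (-1.11), with 3 lower and 1 higher adjusted over the list alone. Of 23 antioxidant genes Prdx1 and Gstp1 (0.91) rose, and of 8 interferon-stimulated genes Bst2 rose (1.53), with the same counts adjusted over the list alone. None of 13 heat shock genes passed by edgeR (7 at an unadjusted p under 0.05) or limma-voom and 2 passed by DESeq2, against 1 higher and 1 lower adjusted over the list alone.

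Among cell death lists, Bnip3l, which encodes a mitochondrial mitophagy and death protein, rose (0.65, edgeR adjusted p = 0.0490) and the other 22 of 23 pro-apoptotic members did not pass. Of these, Bax was at 5.33 ± 0.940 CPM in siCtrl and 9.62 ± 0.283 CPM in siPlat, and Diablo at 20.3 ± 1.07 and 10.5 ± 0.473 CPM; adjusted over the list alone, 1 rose and 1 fell. In ferroptosis and iron handling, the ferritin gene Fth1 rose from 44.5 ± 16.7 to 124 ± 35.2 CPM and Sat1 rose (0.98) among 15 members, with 2 higher adjusted over the list alone. No call was made among 18 anti-apoptotic genes, 28 autophagy and lysosome genes and 23 p53 and DNA damage genes by edgeR, DESeq2 or limma-voom, nor by edgeR adjusted over the list alone. At an unadjusted p under 0.05 these lists held 4, 4 and 8 members by edgeR, against 2096 of all 11136 tested genes. The 4 tested members of necroptosis and pyroptosis, Ripk1 (-0.55), Gsdme (-1.61), Cyld (-0.30) and Nek7 (0.23), did not pass.

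Among metabolic and housekeeping lists, Cox5a (0.98) and Cox8a (0.77), both subunits of cytochrome c oxidase, rose among 55 nuclear-encoded oxidative phosphorylation genes, with 2 higher and 1 lower adjusted over the list alone. Ppargc1b, a coactivator of mitochondrial biogenesis, rose (1.15) among 23 genes of mitochondrial dynamics, with 1 higher and 1 lower adjusted over the list alone. Rpl37 rose (0.97) among 76 ribosomal protein genes on both adjustments, and none of 18 glycolysis and pentose phosphate genes, 30 proteasome genes and 13 small RNA genes passed on either. At an unadjusted p under 0.05 these lists held 2, 4 and 3 members by edgeR; DESeq2 called 0, 0 and 1 of them and limma-voom 0. Among markers of other cells, none of 5 cumulus and granulosa genes passed on either adjustment, by DESeq2 or limma-voom, or at an unadjusted p under 0.05 by edgeR. The blood and immune markers C1qb (-1.04) and Cd68 (-0.30) and the stroma, theca and endothelium markers Kdr (-2.81), Pecam1 (-0.42), Tek (-0.06) and Dcn (-0.09) did not pass; adjusted over the list alone, C1qb and Kdr fell. Of the zygotic genome activation genes, Eif1a fell (-2.62, edgeR adjusted p = 0.0146) but did not pass by limma-voom (adjusted p = 0.0511) or without siCtrl 2 (edgeR adjusted p = 0.0601, lowest over all settings 0.00281), and DESeq2 gave it no adjusted p. On the list alone Eif1a was also the single call, while Sp110 (0.18), Tcstv3 (-0.15) and Tcstv1 (-0.04) did not pass.

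DESeq2 called more members than edgeR in 12 lists, among them plasminogen activation (2 against 1), cohesin and spindle checkpoint (4 against 1), chromatin regulators (4 against 1), the unfolded protein response (3 against 1) and oocyte markers (12 against 8, with 10 by limma-voom). As sets, 0 of 27 lists passed with camera (lowest adjusted p = 0.0930), 5 of them having an unadjusted p under 0.05. Of these 5, ribosomal proteins had a median log2 fold change of 0.24, interferon-stimulated genes 0.62, immediate early genes -0.66, meiotic maturation -0.26 and plasminogen activation, which holds Plat, -0.35. With an estimated correlation 0 lists passed (lowest adjusted p = 0.951) and 0 had an unadjusted p under 0.05, and with fry 0 passed (lowest adjusted p = 0.132) and 3 had an unadjusted p under 0.05. In 20 lists the mixed test of fry, which asks whether members change in either direction, had an adjusted p under 0.05. It does not compare members with other genes, and 2096 of all 11136 tested genes had an unadjusted p under 0.05 by edgeR. The 20 include lists without a called member, such as the proteasome and small RNA machinery (fry mixed adjusted p = 0.0234 in each). The test therefore does not set these lists apart from other genes. Median, mean and camera direction differed in sign in 8 lists, among them Erk1/2 targets and feedback inhibitors (median -0.09, mean 0.31), where Dusp5 was at 0 counts in siCtrl and its fitted value enters the mean.

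The number of called genes rested on each of the 4 libraries, with 157 (72 higher, 85 lower) and 160 called without siCtrl 1 and 2 and 713 and 1145 without siPlat 1 and 2; limma-voom called 414 of the same 11136 genes, and of 14064 genes without the filter edgeR called 581 and DESeq2 657. The calls of Ergic3, Spink2, Sft2d3, Tspan12, Btla and Pigt and of 27 of the 31 called list members ended when a library was left out, among them Gdf9 (edgeR adjusted p = 0.0667 without siCtrl 1 and 0.108 without siCtrl 2, lowest over all settings 1.02e-05) and Dazl (0.117 without siCtrl 1, lowest 1.19e-06), whereas Plat, Mos, Astl and Prdx1 were called in all 11 other settings.

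The second comparison asked how oocytes of aged mice differ from those of young mice, and there was no replicate check because each age was 1 sample. Plat was lower in the aged oocytes, at 3663 CPM (interval 3657 to 3670) against 7193 CPM (7183 to 7202) in the young, a log2 ratio of -0.97 or 1.96-fold. Scaled to ERCC spike-in counts in place of gene totals, the log2 ratio was -2.45, or -1.36 without 21 aged libraries whose mitochondrial share was above 5%. This scaling shifts all genes by nearly the same factor, so the further drop is not particular to Plat. It takes the spike-in per oocyte as equal, which was not checked, and gene counts per ERCC count ran from 18.3 to 147 among young oocytes alone. Per oocyte, the median was 3879 CPM in aged and 7077 CPM in young oocytes, and all 59 aged and all 35 young oocytes had a Plat count. The genes with the highest ratios were mitochondrially encoded: the ribosomal RNA genes mt-Rnr1 (14.8-fold higher in aged) and mt-Rnr2 (11.1-fold), the cytochrome c oxidase genes mt-Co3 (10.7-fold), mt-Co2 (9.13-fold) and mt-Co1 (6.98-fold), and mt-Nd4, mt-Nd3, mt-Nd1, mt-Nd5, mt-Nd2 and mt-Tp. The only nuclear gene among these 12 was the iron storage gene Fth1, at 101 CPM in aged and 9.86 CPM in young (9.35-fold).

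These ratios followed a group of aged libraries that stood apart from the rest. The mitochondrially encoded share of gene counts was above 5% in 21 of 59 aged oocytes (35.6%, exact interval 23.6 to 49.1%) and in 0 of 35 young oocytes, which allows a share of up to 8.57% (3 of 35) and has an exact upper limit of 10.003%. It ranged from 6.78 to 61.6% (median 32.8%) in those 21 and reached at most 2.97% in the other 38 aged and 1.92% in the young oocytes. The 21 libraries had 7385 to 13849 genes with a count against 14724 to 17623 in the other 38. In them Plat was at 1.07 to 76.1 CPM, Gdf9 at 28.7 to 307 CPM and the linker histone gene H1foo at 14.7 to 467 CPM, while the cyclin gene Ccnb1 stood at 731 to 5730 CPM (young oocytes 2169 to 3742) and Fth1 at 59.3 to 965 CPM (young oocytes 3.52 to 16.4).

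**Figure D3:**
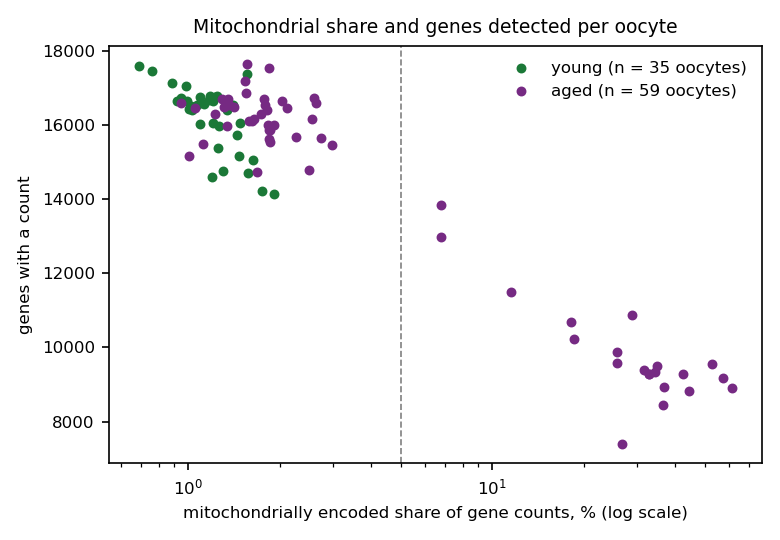
Mitochondrially encoded share of gene counts (percent, log axis) against the number of genes with a count, with 1 point for each of 59 aged and 35 young oocytes and a dashed line at 5%. The 21 aged oocytes right of the line had 7385 to 13849 genes with a count.

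Without those 21 libraries, Plat in the aged sample was at 5007 CPM, a log2 ratio of -0.52 or 1.44-fold lower than young, and Fth1 turned to -0.18. The highest ratios were then those of Gadd45gip1, a mitochondrial ribosome gene (14.2 CPM in young, 64.6 CPM in aged), the splicing gene Snrnp70 (4.20-fold), the actin-binding Tmsb10 (3.89-fold), Zfp951, Ccdc58, the telomere gene Terf1, the ribosomal protein genes Rpl17 (3.01-fold) and Rps29, Taf1b, the spindle gene Tacc3, Rars and Cenpq. The lowest were those of Vmn1r43 (3.12-fold lower), Mid1 (2.14-fold), the co-chaperone gene Dnaja4, Serpinb3a, Rnf165, Ube2s, Efna5, the RNA-binding protein gene Igf2bp3 (1.86-fold), Mfsd9, Enpp2, Repin1 and Ammecr1l. With all oocytes, Vmn1r43 (3.07-fold lower), Dnaja4 (2.76-fold), Serpinb3a (2.52-fold), Ube2s (2.36-fold), Mfsd9 and Repin1 were also among the 12 lowest, with Cherp, Cgn, Ube2h, Lrrc8a, Steap4 and Ccdc85c. The median log2 ratio of all genes with at least 5 CPM was -0.07 with all oocytes and 0.08 without the 21 libraries.

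Of 26 lists, 4 had a median above the range of 95% of random lists with all oocytes (mitochondrially encoded genes, ribosomal proteins, Erk1/2 cascade and small RNA machinery) and 0 below it; without the 21 libraries it was 6 (mitochondrially encoded genes, ribosomal proteins, oxidative phosphorylation, proteasome, oocyte markers and egg activation) and 0. The list of mitochondrially encoded genes had a median log2 ratio of 2.98, above all 10000 random lists, and of 0.32 (percentile 99.9) without the 21 libraries. Cytosolic ribosomal proteins had a median of 0.25 (percentile 99.9; 0.06 and percentile 91.6 with the median over oocytes), with 27 members higher and 13 lower, and of 0.52 without the 21 libraries, with 40 higher and 3 lower. Nuclear-encoded oxidative phosphorylation moved from 0.11 (percentile 94.6; -0.06 with the mean over oocytes) to 0.44 (above all random lists), where Atp5e was 2.35-fold and Sdhd 2.28-fold higher in aged oocytes. Proteasome subunits moved from -0.05 (percentile 68.7) to 0.31 (percentile 99.9), with Psmc2 at 2.42-fold. Oocyte markers with maternal effect genes moved from -0.12 (percentile 77.1) to 0.21, with 21 members higher and 8 lower. Gdf9 stayed lower in aged oocytes, at 5635 CPM with all oocytes and 7671 CPM without the 21 libraries against 10368 CPM in young. Egg activation and calcium signalling moved from 0.08 (percentile 92.9; -0.04 with the mean over oocytes) to 0.33 (percentile 99.7).

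Erk1/2 cascade components had a median of 0.15 in both sets, at percentile 99.0 with all oocytes and 87.7 without the 21 libraries, and were at 0.04 (percentile 88.5) when thinned and 0.07 (97.1) with the median over oocytes, both inside the range of 95% of random lists. Among them, the phosphatase gene Ptpn11 moved from 0.84 to -0.05. Pro-apoptotic genes had a median of -0.26 (percentile 3.74), with 4 members higher and 12 lower, and of -0.06 (percentile 3.30) without the 21 libraries; Trp53 was at -0.77, then -0.41. Anti-apoptotic genes moved from -0.19 (percentile 24.99) to 0.01 (percentile 32.7), where Birc5 was higher (0.58, then 0.82) and Birc3 lower (-0.83, then -0.53). Plasminogen activation had a median of -0.28 (percentile 10.96), with 1 member higher and 9 lower, and of 0.01 (percentile 32.3) without the 21 libraries. Erk1/2 targets and feedback inhibitors were at 0.06 (percentile 84.5; -0.01 with the mean over oocytes), immediate early genes at -0.14 (29.7; 0.0045 with the median over oocytes) and PI3K with Akt and mTOR at 0.09 (95.5). Ferroptosis and iron handling was at -0.30 (5.02) although it holds Fth1, and at -0.08 (8.65) without the 21 libraries. Autophagy and lysosome was at -0.19 (10.6), then -0.05 (6.16). The p53 and DNA damage list was at 0.05 (82.9), and at -0.13 at a minimum of 1 or 20 CPM. The unfolded protein response was at -0.30 (3.31), which turned to 0.11 (83.5) without the 21 libraries.

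Among the other lists with all oocytes, small RNA machinery had a median of 0.30 (percentile 99.0), with Drosha 2.56-fold higher in aged oocytes. Heat shock proteins were at 0.07 (91.1; -0.04 at a minimum of 1 CPM), mitochondrial dynamics at 0.11 (89.8; -0.13 at a minimum of 20 CPM) and maternal mRNA clearance at -0.0030 (93.2), where the decapping gene Dcp2 was 3.53-fold higher. Antioxidant defence was at -0.0070 (69.5), chromatin regulators at -0.10 (61.8), meiotic maturation at -0.24 (16.7), glycolysis and pentose phosphate at -0.20 (10.7), and cohesin and spindle checkpoint at -0.31 (6.40). Without the 21 libraries chromatin regulators turned to 0.04, glycolysis to 0.04, cohesin and spindle checkpoint to 0.0099 and maternal mRNA clearance to 0.03 (67.4). Meiotic maturation was then at -0.12 (4.58). With totals without mitochondrially encoded genes, which moved the median of the compared genes from -0.08 to 0.04, the medians of antioxidant defence (0.11), chromatin regulators (0.02), maternal mRNA clearance (0.12), oocyte markers (0.0076) and the proteasome (0.07) turned positive. Lists with under 5 members gave single values only. Cumulus and granulosa markers Kitl (0.56), Nr5a2 (0.51) and Cyp19a1 (-0.50) lay on both sides of 0, as did the interferon-stimulated genes Ddx58 (1.06), Irf1 (0.78), Stat2 (-0.13) and Bst2 (-0.14), of which all 4 were above 0 without the 21 libraries (Stat2 0.03, Bst2 0.25). C1qb of the blood markers was at -0.59, and at -0.26 without the 21 libraries. Pecam1 of the stroma, theca and endothelial markers was at -1.01, in a list with 1 member higher and 2 lower (median -0.38). Without the 21 libraries that list had 0 higher and 2 lower. The necroptosis genes Ripk1, Nek7 and Cyld were at 0.73, 0.24 and -0.02 (0.33, -0.03 and -0.40 without the 21 libraries). The zygotic activation genes Sp110, Tcstv1 and Tcstv3 were at -0.17, -0.09 and 0.03, turning to 0.14, 0.34 and 0.43 without the 21 libraries.

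**Figure D4:**
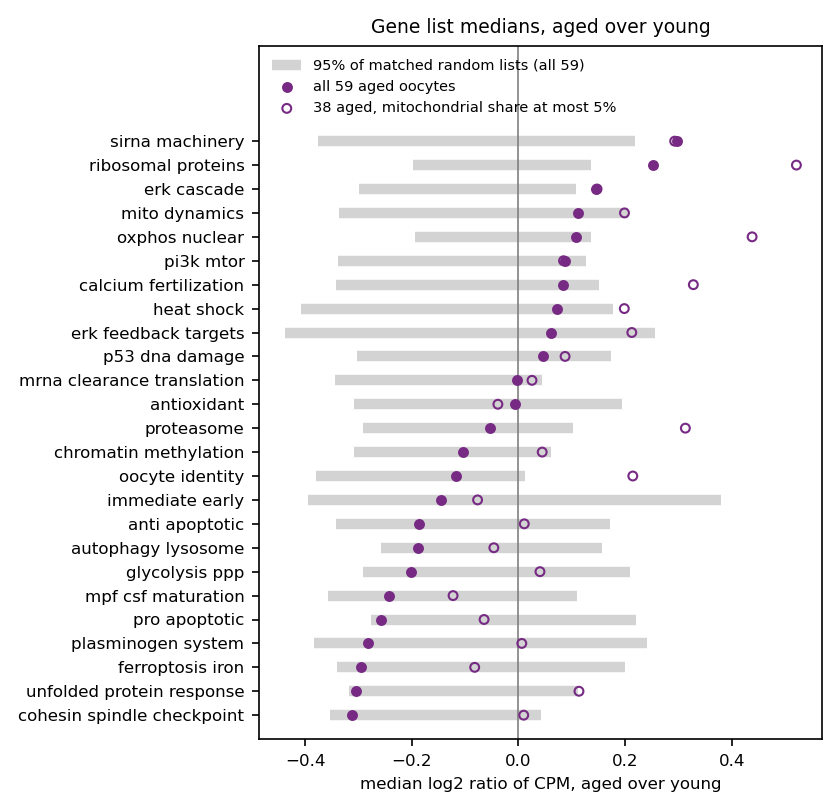
Median log2 ratio of CPM, aged over young, for 25 gene lists with at least 5 members (mitochondrially encoded genes are left out at 2.98), with all 59 aged oocytes (filled) and with the 38 at a mitochondrial share of at most 5% (open). Grey bars hold 95% of matched random lists for all 59 oocytes and do not apply to the open points; ribosomal proteins lie at 0.25 and 0.52.

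The third comparison asked whether genes called in the knockdown differed with age in the same direction, and no library was shared between the data sets. Of the 157 genes lower in siPlat, 126 could be compared, with a median age log2 ratio of -0.18 (percentile 7.89 of matched random lists, but 2.72 with the mean and 0.460 with the median over oocytes, the last below the range of 95% of random lists), 85 lower and 41 higher in aged oocytes. Of the 237 genes higher in siPlat, 188 had a median of -0.0027 (percentile 99.5, but 96.6 and inside that range when thinned), 96 lower and 92 higher, where the median of all 7753 compared genes was -0.08. Mos, Astl and Gdf9, which fell in siPlat, were at -0.62, -1.01 and -0.88 in the age comparison and at -0.17, -0.57 and -0.43 without the 21 libraries. Prdx1 and Dazl, which rose in siPlat, were at -0.28 and -0.0098, and at 0.14 and -0.04 without the 21 libraries. Without the 21 libraries the medians were 0.06 (percentile 75.2) for genes lower in siPlat and 0.11 (percentile 96.0) for genes higher in siPlat. Some changes of siPlat also marked the 21 libraries themselves, with Mos at a median of 8.92 CPM (1150 in young), Gdf9 at 88.9 (10527) and Fth1 at 210 (9.59). Dazl, which rose in siPlat, was at 1418 CPM there and 1307 CPM in young oocytes. Across genes, which are not independent replicates, Pearson's r between the log2 changes of the comparisons was 0.02 and Spearman's rho 0.02.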

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

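The tests on the 21 aged libraries and the tests on copies and on counts of called genes on chromosome 4 were chosen only after the result was seen; the others in this part were written down before.

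Outside the gene counts, ERCC spike-in counts made up a median of 3.88% of counts per aged oocyte and 1.55% per young oocyte, and were used above only for the scaled ratio of Plat. Gene counts per ERCC count had a median of 24.8 in aged and 63.7 in young oocytes, and of 29.5 and 15.2 in the 38 aged oocytes with a mitochondrial share of at most 5% and the 21 above it.

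In 21 of the 59 aged libraries the mitochondrially encoded share was above 5%, while Plat was at 1.07 to 76.1 CPM and Gdf9 at 28.7 to 307 CPM. Cells of another type in place of an oocyte are not decided by the 3 lists of markers of other cells. The summed CPM of cumulus, blood and stroma markers had a median of 80.7 in these libraries and 284 in young ones. None of the 21 was above the young maximum of this sum (highest 285 against 359 CPM). Because the young sum comes from single oocytes, it is no measure of other cells, and a sum below it cannot decide. Oocyte RNA was present in the 21 libraries, where oocyte markers summed to 2181 to 30227 CPM, against 42387 to 55364 CPM in young ones. Dazl had a median of 1418 CPM there and 1307 CPM in young oocytes, whereas Mos had 8.92 and 1150 CPM. In 4 of the 21, the blood and immune sum (25.9 to 194 CPM, led by Hba-a1 in the highest) was above the young maximum of 21.8 CPM, and added blood RNA stays open there. Less RNA of all genes alike is argued against, since 37.6% of the 1953 genes with at least 100 CPM in the median young oocyte were 4-fold or more lower, and 28.6% were at or above the young median. A collection or library batch stays open: along the order of the 59 columns, libraries above and at most 5% alternated in 7 runs, counted over both kinds, where the lowest of 10000 shuffles gave 15 runs and the median 28. The age of the mice, or selective loss of some transcripts in dying oocytes, may also be the source and was not tested, since each age was 1 sample and age and batch cannot be separated.

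Among genes called in the knockdown, 12 of 42 tested genes of a segment of chromosome 4 with Pramel and Zfp genes, drawn around these calls, were called (10 higher, 2 lower). Besides, 5 genes had almost no counts in 1 group: Pramel27, Phtf1os and 1700049E17Rik1 in siCtrl, Agbl2 and Rassf4 in siPlat. A difference of genetic background between the pools could give such genes; 165 called genes had a called neighbour of another family within 1 Mb, against a median of 154 in shuffles with a range of 95% reaching 178, which leaves it open. Chance loss of low counts is argued against for the segment, where 9 of the 12 called genes had at least 50 counts in each of the 4 libraries, but stays open for the 5 genes: pairs of libraries across groups held at least 12 genes with almost no counts in a single library of the pair and pairs within a group 4 and 7, and each pairing of a siCtrl with a siPlat library set against the other 2 held 1 gene with almost no counts in a pair, in 1 case (Gm13363) at 121 and 141 CPM in the libraries that had it. Reads shared between copies cannot be told apart from a change either, because the summed CPM of the segment's family genes differed by 468, close to the larger SD (3059 ± 16.0 in siCtrl, 3527 ± 416 in siPlat, SD, n = 2 each). In young single oocytes the median was 196 CPM for Pramel27, 0 CPM for Phtf1os and 1700049E17Rik1, 1.28 CPM for Agbl2 and 0.222 CPM for Rassf4.

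Ribosomal protein, nuclear oxidative phosphorylation and proteasome genes were higher in the aged oocytes that remained without the 21 libraries. Transcript length is argued against as the whole cause, since with random lists matched on expression and length the lowest percentile of the 3 lists was 99.8. GC content is argued against in the same way, with a lowest percentile of 99.95. Matched on length, random lists had medians of 0.21, 0.18 and 0.08, against 0.52, 0.44 and 0.31 for the 3 lists, so a part through length stays open. The random lists draw each gene independently, while list members may vary together (estimated correlation in the pools 0.60, 0.33 and 0.15). The percentiles are therefore no measure of chance. A batch stays open because each age was 1 sample, and an effect of the age of the mice is a hypothesis that these data could not separate from it.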

How the results depend on the processing

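The alternatives without the 21 libraries of high mitochondrial share, with ERCC scaling (also without those libraries) and without the chromosome 4 segment were chosen after seeing the data; the others were planned. Where a value moved, the cause was not tested.

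In the knockdown, Plat was called in all 11 other settings, with log2 fold changes from -3.50 to -3.09 and adjusted p from 7.47e-62 (DESeq2) to 2.19e-05, and 19 of the 25 named genes kept their call in all of them. Ergic3, Spink2, Sft2d3, Tspan12, Btla and Pigt lost it when a library was left out. Ergic3 had log2 fold changes of -1.28, -2.19 and -1.90 without siCtrl 2, siPlat 1 or siPlat 2. Without siCtrl 1, Sft2d3, Btla and Pigt were at 1.66, -2.11 and -1.85, and without siCtrl 2 Tspan12 was at 1.58. Spink2 was at 2.00 and 2.85 without siPlat 1 or siPlat 2. It also lost its call without the filter (edgeR adjusted p = 0.0725) and with the replicate number as a block (edgeR adjusted p = 0.0975). Without the chromosome 4 segment and genes with almost no counts in a group, 366 genes were called (222 higher, 144 lower). DESeq2, without the filter, called 657 genes, 427 of them higher. With upper-quartile scaling Dusp1, Deptor, Tle6 and Khdc3 lost their call. Genes called lower numbered 240 with no filter and 239 with the stricter filter, where other numbers of genes were tested (14064 and 8240). Leaving out a library, with the lone sample assumed to vary like the other group, gave 157 (without siCtrl 1), 160 (siCtrl 2), 713 (siPlat 1) or 1145 (siPlat 2) called genes, sharing 124, 125, 363 and 376 with the 394; 72 to 645 were higher, 68 to 500 lower, 157 to 470 changed at least 2-fold, and 0 to 2 lists passed camera. The other scalings called 401 (RLE) and 379 (upper quartile) genes. Over named and list genes, 1389 values kept their side of the threshold, 87 gained a call and 72 lost it, and 12 reversed, all of genes not called. With each library left out these ranged from -2.33 to 0.63 (Cd68), -6.25 to 0.46 (Star), -0.52 to 0.52 (Cyp19a1), -0.058 to 0.66 (Ftl1), -0.41 to 0.22 (Tek), -1.17 to 0.57 (Dcn), -0.32 to 0.059 (Tcstv3) and -0.32 to 0.25 (Tcstv1).

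With the replicate number as a block, 273 genes were called (158 higher, 115 lower), 267 of them shared, and Spink2 and 8 of 31 called list members lost their call. The labels do not say that the numbers pair samples, and same-numbered samples deviated with a correlation of -0.06.

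For age, the log2 ratio of Plat was -1.16 with the mean and -0.87 with the median over oocytes, -0.95 thinned, -0.999 with TMM factors, -0.85 with totals without mitochondrial genes, -1.0002 without the deepest oocytes, -0.52 without the 21 libraries and -2.45 scaled to ERCC counts (-1.36 without the 21 libraries). Totals without mitochondrial genes moved the median of the compared genes from -0.08 to 0.04. Without the 21 libraries the medians were 0.011 for anti-apoptotic genes, 0.0063 for plasminogen activation (-0.49 with the mean) and -0.064 for pro-apoptotic genes; Erk1/2 cascade components were at 0.040 thinned and 0.27 with totals without mitochondrial genes. Genes lower in siPlat moved to -0.31 (mean), -0.061 (totals without mitochondrial genes) and 0.060 (without the 21 libraries). Genes higher in siPlat moved to -0.10 (mean) and turned to 0.015 (median), 0.12 (totals without mitochondrial genes) and 0.11 (without the 21 libraries). Fth1 turned to -0.18 without the 21 libraries, and the other 23 of 24 genes named for age kept their direction in all settings but ERCC scaling, which was run for Plat only. Of the list medians, 235 stayed within their spread, 16 of them with the other sign, and 50 moved, 17 of them with the other sign. With all oocytes, Erk1/2 cascade components came inside the range of 95% of random lists with the median (percentile 97.1), thinned (88.5) and at a 20 CPM minimum (93.7), ribosomal proteins with the median (91.6) and small RNA machinery at 20 CPM (97.2). PI3K with Akt and mTOR lay above it with the mean (98.8) and thinned (98.7), oxidative phosphorylation at 1 CPM (98.5) and heat shock at 20 CPM (97.7), and the unfolded protein response below it with the mean (1.65) and a pseudocount of 5 (2.28) and pro-apoptotic genes at 1 CPM (1.24). A minimum of 100000 counts and 3000 genes per oocyte removed no oocyte and gives no value. The thinned median number of genes with a count was 15440 in 50 aged and 15354 in 35 young oocytes, against 15990.0 and 16539 in the same oocytes at full depth.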

Other observations

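Plat stood at 441 and 439 CPM in the siCtrl pools and at a median of 7077 CPM in single young oocytes. The tables of pools and of single oocytes were made from separate libraries, and the difference was not tested. Mos was at 797 CPM in siCtrl and 1169 CPM in the young sample, and Gdf9 at 2920.5 and 10368 CPM.

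In the 21 aged libraries with a mitochondrial share above 5%, some abundant oocyte transcripts were near the CPM of young oocytes and others were far below it. CPM are shares of a library and no amounts, and gene counts per ERCC count had a median of 15.2 there and 63.7 in young oocytes. A CPM near that of young oocytes therefore does not show that the amount of a transcript was kept. Spin1 had a median of 10896 CPM there and 15158 CPM in young oocytes, and Dazl 1418 and 1307 CPM, whereas Mos had a median of 8.92 CPM against 1150.0 CPM and Zar1, an oocyte RNA-binding protein gene, 5.89 against 1013 CPM.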
